A study of Mus musculus with 12 samples.

How the data were processed

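Open chromatin was measured by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in 12 libraries of cells sorted from endpoint SHH medulloblastomas of Ptch1+/- mice. SHH medulloblastoma is a cerebellar tumour driven by hedgehog signalling, and Ptch1 encodes the receptor that restrains the pathway. Per the labels, eGFP marked SOX2+ stem-like cells and SOX2- bulk cells, and RFP separated cycling MKI67+ from MKI67- cells among the SOX2+ cells. Per the labels' protocols, 35000 to 50000 cells entered each reaction, with equal numbers of positive and negative cells within a sort. Libraries were sequenced as single-end reads of 50 bp. Per the submitters' processing notes, reads were aligned with Bowtie2 to mm10 and peaks were called with MACS2 for each library alone. Versions, settings, duplicate handling and any correction for the transposase offset were not given in the sources used here. The replicates are not stated to come from separate animals, so the p-values measure the spread between these samples, which may be technical.

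The deposited lists were used as they were, with no peak removed and no value rescaled. Each list gave a position, a score, a fold ratio over the local background, a -log10 p-value, a -log10 q-value and a summit per peak, all made by the authors with their peak caller. The score was the -log10 q-value of the authors on a larger whole-number scale. Score and fold belong to a single list and were used only to rank peaks within that list. Read counts were not used here, so the sequencing depth is unknown and the number of peaks in a list stood in for the depth of peak calling. Because peaks were called per library, a peak absent from a list may lie just under that list's threshold. The lists held peaks on 19 autosomes and chromosome X.

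Peaks of all 12 lists that overlapped by at least 1 bp were merged into 44242 regions. Similarity of a pair of lists was the Jaccard index in base pairs, which is shared length over joint length. A region exclusive to a SOX2 group had a peak in at least 3 of 4 libraries of that group and in 0 of 4 of the other, and for the MKI67 groups the requirement was 2 of 2 against 0 of 2. Groups were compared by two-sided exact permutation tests over every assignment of libraries to groups. The test of similarity was one-sided instead, for a larger excess within groups, over 35 splits in the SOX2 sort and 3 in the MKI67 sort. With 4 libraries against 4 the smallest p is 0.0286, and with 2 against 2 it is 0.333, so the latter cannot pass 0.05. By chance 2.86% of comparisons of 4 with 4 show groups that do not overlap. Where a result was a count, it was recomputed for all 35 ways to split the 8 libraries of the SOX2 sort 4 against 4, the real split included.

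Each peak was assigned to the nearest of 21631 protein-coding genes when its midpoint lay inside the gene span or within 100 kb of it. The gene table of GRCm38.p6, which has the coordinates of mm10, held gene spans without strand, exons or transcription start sites. Distance to the nearest gene span therefore replaced the planned distance to the nearest start site, and peaks within 1 kb of either end of a gene replaced the planned promoter class. Peaks per gene were tested with limma 3.58.1 (lmFit and eBayes with trend) on log2(peaks per gene + 1). The fit held all 12 libraries, the 4 groups and the log10 of each library's total peaks. Genes with a peak in at least 2 libraries were tested, p-values were adjusted by Benjamini and Hochberg over all genes tested, and an adjusted p under 0.05 was the threshold. The log2 differences depend on the pseudocount of 1, most of all where a group is listed at 0. Tested beforehand on simulated counts, the fit made no false call and missed nearly all changes of 4-fold and most of 8-fold. With 2 libraries per group it missed nearly all of both. The simulated counts were drawn independently around means proportional to list length, and no run made more than 26 calls. Real lists departed from this, since their gene-end share changed with length, so false calls in them were not measured.

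Gene lists, 18 in number, were fixed before the data were examined and 355 of their 356 symbols matched the gene table. They held markers of granule neuron progenitors, stem and progenitor cells, the oligodendrocyte lineage, astrocytes and Bergmann glia, neuronal differentiation, endothelial and mural cells, microglia and macrophages, lymphocytes, fibroblasts and meninges, and ependymal and ciliated cells. They further held the BMP and TGF-beta, hedgehog, Wnt and Notch pathways, the cell cycle, cell cycle inhibitors and quiescence, immediate early genes and housekeeping genes. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which asks whether the genes of a list move on balance in one direction without comparing them with other genes. Adjusted p-values of lists are over the 18 lists of a comparison.

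Which genes to name followed a rule set before the data were examined. It took the 12 genes per direction with the smallest p among those past the threshold, or 6 per direction where fewer passed, then Sox2, Mki67, Olig2, Atoh1, Gli1 and Gfap, and up to 4 members of each list by limma statistic. The rule gave 95 genes for the SOX2 sort and 84 for the MKI67 sort. Of these, 59 and 28 are described, some genes not being reported here, and this smaller choice was made after the values were seen, as was the addition of Ptprz1. Where genes of the MKI67 sort were tied, the first in alphabetical order were taken. Regions named per class were those with the highest mean score percentile within their lists.

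Similarity, exclusive regions, the gene fit, the lists and their alternative settings were chosen before the data were examined. Added later were the shortest list of each SOX2 group left out, all alternatives for the SOX2 exclusive regions in the MKI67 lists and an exact permutation of peaks at list genes. The comparison of chromosomes was also added after the data had been seen, first by the fold ratio and, after that had shown no shift of chromosome 13, by the score, since a fold over the local background can hide a change shared with that background. The bound at 80 Mb was chosen from peak shares along the chromosome before scores by part were computed, and those at 60 and 70 Mb from the scores. Shares of 30 sequence motifs had been planned and were not run, because they need a reference genome. The analysis used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and R 4.3.3.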

Results

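Accessible chromatin was profiled in SOX2- cells (4 libraries), SOX2+ cells (4 libraries), SOX2+/MKI67- cells (2 libraries) and SOX2+/MKI67+ cells (2 libraries) of mouse SHH medulloblastoma. The design asks how open chromatin of the SOX2+ stem-like cells differs from that of the tumour bulk, and how cycling SOX2+ cells differ from those that do not cycle. The lists held 7009, 26206, 12660 and 21682 peaks in SOX2- replicates 1 to 4 and 16788, 9377, 19636 and 25272 in SOX2+ replicates 1 to 4. SOX2+/MKI67- replicates held 19229 and 17615 peaks, and SOX2+/MKI67+ replicates 18738 and 24694. SOX2+ libraries had 17768 ± 6612 peaks (SD, n = 4) and SOX2- libraries 16889 ± 8666 (n = 4), a difference within the spread of replicates (exact permutation p = 0.886). Covered length was 7.52 ± 3.23 Mb and 7.09 ± 4.00 Mb (exact p = 0.886), and median peak width 382 ± 20.4 bp and 372 ± 23.7 bp (exact p = 0.571). The sign of the difference in peak number depended on single libraries, as it was -2414 without SOX2- replicate 1, -531 without SOX2- replicate 3 and -1622 without SOX2+ replicate 4.

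The share of peaks within 1 kb of a gene end was 74.9% in the shortest list and 37.4% in the longest. Of the 44242 merged regions, 27.3% lay at gene ends, 38.5% elsewhere inside gene spans and 34.2% between genes. The 5444 regions found in all 8 libraries of the SOX2 sort were mostly at gene ends (82.5%). With 7009 peaks from every list the gene-end share was 70.9 ± 1.16% in SOX2+ and 71.9 ± 3.30% in SOX2- libraries (n = 4 each, exact p = 0.571).

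**Figure D1:**
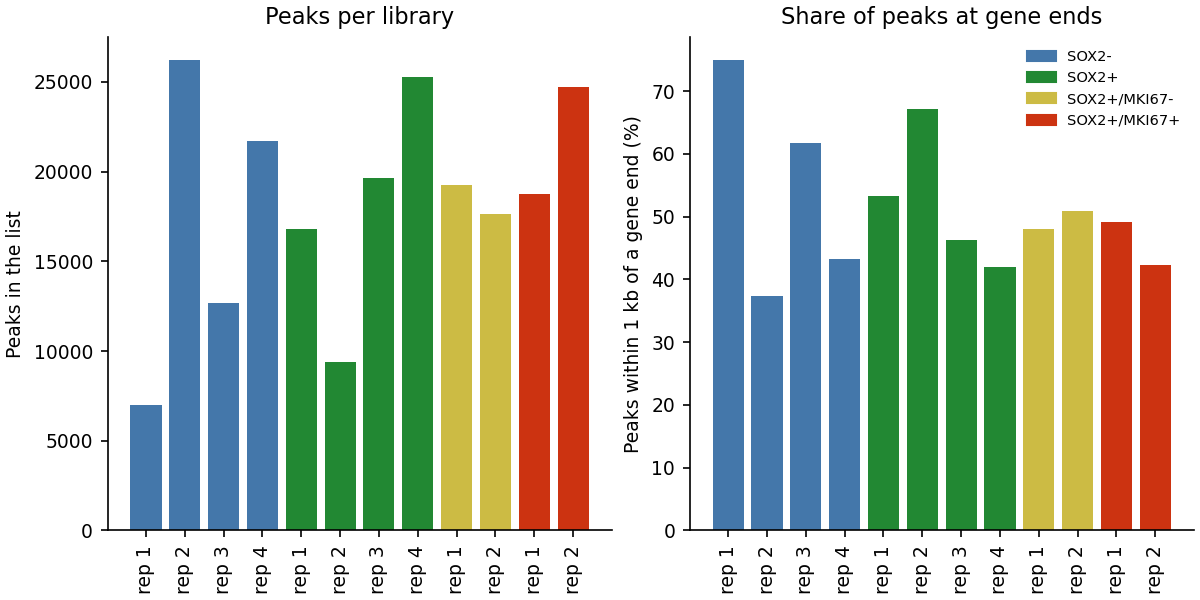
Number of peaks (left) and percent of peaks within 1 kb of a gene end (right), with 1 bar per library coloured by sorted population. Lists ranged from 7009 to 26206 peaks, and the gene-end share was highest in the shortest list (74.9%).

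Open regions found in every library of the SOX2 sort lay mostly at gene ends, and those found in a single group lay mostly away from them. Loci of stem-cell, oligodendrocyte and astrocyte genes, among them Sox2, Fabp7, Olig2 and Nkx2-2, carried more peaks in SOX2+ cells, and those of granule neuron progenitor and neuronal genes, among them Nhlh1, Boc, Reln and Map2, carried fewer. These list-wide differences passed with the preset correlation of camera, and none passed with an estimated correlation (adjusted p = 0.0769 to 0.131 with an estimated correlation). Of 12541 genes tested with limma, 233 passed, with 181 higher and 52 lower in SOX2+ cells. Of these, 85 had a peak in all 4 libraries of one group and in 0 of the other. The value was identical within every group at 44 of the 233, where the test rests on the spread of other genes. Of the 37 passing genes described here, every SOX2+ library lay on the same side of the SOX2- mean in 37. The groups did not overlap in 28 of these 37, and in 147 of the 233. At Boc and Map2, 0 of 4 SOX2+ libraries lay beyond every SOX2- library.

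The sort marker itself was among the genes that rose. Sox2, a transcription factor of neural stem cells on chromosome 3, had 4.25 peaks per library in SOX2+ and 0.75 in SOX2- cells, a log2 difference of 1.49 ± 0.25 (SE, adjusted p = 0.0198). Its gene-end region at chr3:34649337-34650204 was listed in 4 of 4 SOX2+ and in 3 of 4 SOX2- libraries. Regions at chr3:34532429-34532845, 117 kb before the gene, and chr3:34722302-34723038, 70.2 kb after it, were listed in 4 of 4 SOX2+ and 0 of 4 SOX2- libraries, and in all 4 MKI67 libraries. Mki67, a gene of cycling cells, had a log2 difference of -0.55 (adjusted p = 0.268).

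Stem and progenitor loci gained peaks as a list (median log2 difference 0.60, 15 of 20 members positive, camera adjusted p = 9.01e-04). The call was lost with an estimated correlation (adjusted p = 0.0769 with an estimated correlation) and with equal peak numbers (0.53). Sox2, Sox21, Fabp7 and Ptprz1 were among the members that rose and 15 did not pass, while 9 rose and 3 fell when adjusted over the list alone. Sox21, a relative of Sox2, was listed at 2.25 peaks in SOX2+ against 0 in SOX2- cells (log2 difference 1.57, adjusted p = 0.0076), and Fabp7, a fatty acid binding protein of radial glia, at 1.0 against 0 (adjusted p = 0.0054). The Fabp7 region at its gene end was chr10:57784340-57785003. Ptprz1, a receptor phosphatase of glial progenitors, had 4.5 against 1.25 (adjusted p = 0.0228).

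Oligodendrocyte lineage loci gained peaks (median 0.44, 12 of 15 positive, camera adjusted p = 0.00125, and adjusted p = 0.131 with an estimated correlation, which ends the call). Olig2 and Nkx2-2, both transcription factors that specify the lineage, rose and 13 members did not pass. Olig1 and Cspg4 joined them when adjusted over the list alone, which gave 4. Olig2 had 3.75 peaks against 1.0 (log2 difference 1.26 ± 0.20, adjusted p = 0.0118) and Nkx2-2 had 1.75 against 0 (1.44, adjusted p = 0.00537). The neighbouring Olig1 had 4.25 against 1.5 (1.14, adjusted p = 0.0832), and Cspg4, which encodes the NG2 proteoglycan of oligodendrocyte progenitors, had a log2 difference of 1.36 (adjusted p = 0.141). On chromosome 16 the regions 91191235-91192217, 91233286-91234048, 91262521-91263255 and 91305133-91306134 were listed in 4 of 4 SOX2+, 0 of 4 SOX2- and all 4 MKI67 libraries. The Olig2 gene-end region, 91224954-91225706, was listed in 1 of 4 SOX2- libraries. The Nkx2-2 region chr2:147180625-147181292 was listed in 4 of 4 SOX2+ and 0 of 4 SOX2- libraries.

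**Figure D2:**
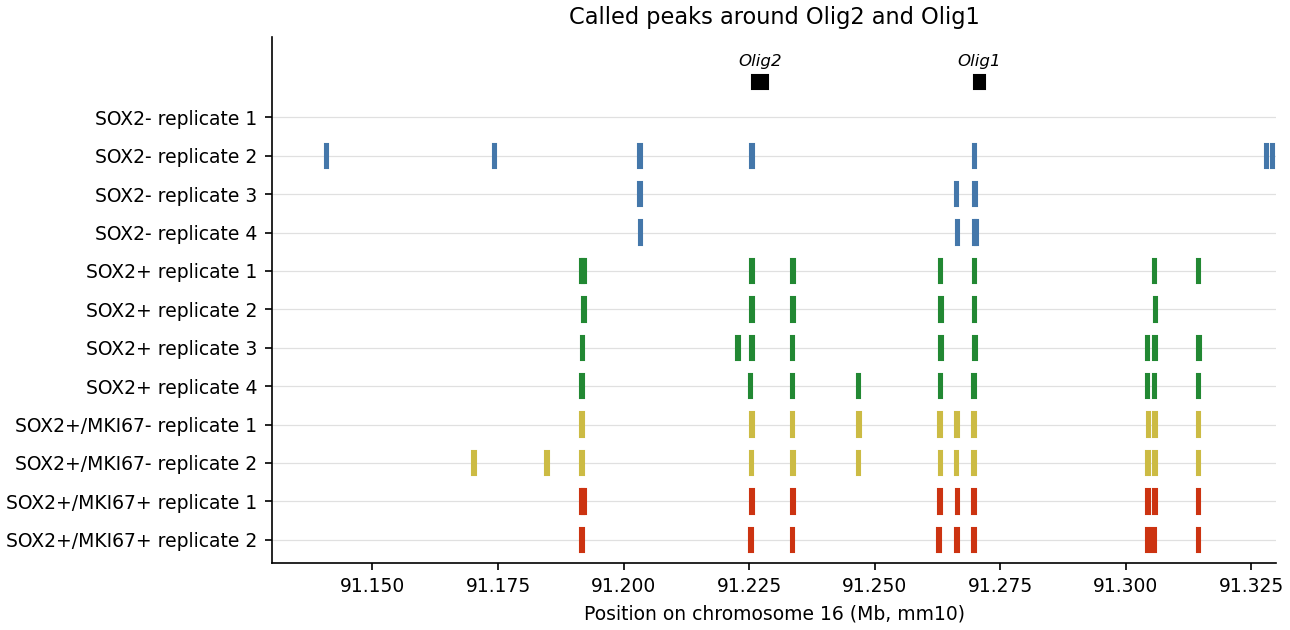
Called peaks (boxes) in each of the 12 libraries by position on chromosome 16 (Mb, mm10), coloured by sorted population, with the spans of Olig2 and Olig1 on top. The 4 SOX2- libraries have 0 peaks in 4 regions that all 8 SOX2+ libraries of both sorts have.

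Astrocyte and Bergmann glia loci also gained peaks as a list (median 0.45, 15 of 16 positive, camera adjusted p = 0.00136). This call too was lost with an estimated correlation (adjusted p = 0.0905 with an estimated correlation) and with equal peak numbers (0.53). Aldh1l1, a folate enzyme of astrocytes, was the 1 member that rose, listed at 2.0 against 0 (log2 difference 1.45, adjusted p = 0.0469), and 15 did not pass. When adjusted over the list alone 4 rose. The others were Id3 (0.88, adjusted p = 0.100 over all genes), S100b (1.13, adjusted p = 0.106) and the glutamate transporter gene Slc1a2 (0.69, adjusted p = 0.161). Gfap, the intermediate filament of reactive astrocytes, had a log2 difference of 0.03 (adjusted p = 0.979), which was negative without SOX2- replicate 2 (-0.018), SOX2- replicate 3 (-0.074), SOX2+ replicate 1 (-0.086) or SOX2+ replicate 4 (-0.142).

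Granule neuron progenitor loci lost peaks in SOX2+ cells (median -0.49, 19 of 20 members negative, camera adjusted p = 3.37e-05, and adjusted p = 0.0769 with an estimated correlation, which ends the call). These progenitors are the cells of origin of SHH medulloblastoma. Nhlh1, Boc and Sfrp1 fell and 17 members did not pass. Among its members 8 fell when adjusted over the list alone. Nhlh1, a basic helix-loop-helix factor of newborn granule neurons, was listed at 0 in SOX2+ and 1.75 in SOX2- cells (log2 difference -1.46, adjusted p = 0.014). Its regions at chr1:172057454-172058024 and chr1:172060739-172061183 were listed in 3 of 4 SOX2- and 0 of 4 SOX2+ libraries. Boc, a hedgehog co-receptor, had 2.0 against 5.75 peaks (-1.04, adjusted p = 0.029), and Sfrp1, a secreted Wnt antagonist, 0.5 against 2.25 (-1.19, adjusted p = 0.042). Atoh1, the factor that specifies granule neuron progenitors, had 2.0 against 3.25 peaks (-0.83, adjusted p = 0.349) and passed only with equal peak numbers and with a peak in at least 4 libraries, and Barhl1 a log2 difference of -1.21 (adjusted p = 0.103).

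Neuronal differentiation loci lost peaks as well (median -0.39, 15 of 19 negative, camera adjusted p = 0.00238, and adjusted p = 0.131 with an estimated correlation, which ends the call). Reln and Map2 fell, 17 members did not pass, and adjusted over the list alone the same 2 fell. Reln, which encodes the secreted glycoprotein reelin made by granule neurons, had 1.25 peaks in SOX2+ and 6.0 in SOX2- cells (log2 difference -1.83, adjusted p = 0.010). Regions at chr5:21949032-21949694 and chr5:22093134-22093743 were listed in 4 of 4 SOX2- and 0 of 4 SOX2+ libraries. Map2, a microtubule protein of dendrites, had a log2 difference of -0.63 (adjusted p = 0.0327). The growth-cone genes Stmn2 (-1.14, adjusted p = 0.187) and Gap43 (-1.06, adjusted p = 0.198) did not pass.

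Further genes were among those with the smallest p-values. Listed at 0 in SOX2- cells were S1pr2, a receptor for sphingosine-1-phosphate with 2.0 peaks in SOX2+ cells (log2 difference 1.58 ± 0.147), Mt1, a metallothionein with 2.25, and Rnf182, a ubiquitin ligase gene with 2.0. Fa2h, whose enzyme hydroxylates fatty acids of myelin lipids, had 3.0 against 0.25 (1.71). Dock10 (1.56), Myrip (1.64), Zfp648 (1.62), Unc80 (1.36), Susd5 (1.42), Cyp2j9 (1.42) and 4930432M17Rik (1.41) also rose. Each of these had an adjusted p of 0.00537. Among genes that fell, Lhx1, a LIM homeobox factor, had 0.25 peaks in SOX2+ and 4.0 in SOX2- cells (-2.02). Cdk6, a kinase of the G1 phase, had 0.75 against 4.0 (-1.67), Opa1, a mitochondrial fusion gene, 2.0 against 6.25 (-1.37), Cacng2, a subunit that regulates AMPA receptors, 1.0 against 3.75 (-1.25), and Cdk15 was listed at 0 against 1.75 (-1.45). Tmem178b (-1.51), Btbd11 (-1.33), Aldoart1 (-1.17) and Cenpk, Zfp511, Pou5f2 and 9230019H11Rik (-1.0 each) fell too, with adjusted p-values of 0.00537 to 0.00788 over the 12. The direction of Cacng2 turned with equal peak numbers (0.354), the upper part of each list (0.275) and a peak in at least 4 libraries (0.446), and that of Tmem178b (0.149) and Opa1 (0.005) at gene ends.

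Among signalling pathways, the BMP and TGF-beta list passed with a small shift (median 0.11, 14 of 22 positive, camera adjusted p = 0.0386, and adjusted p = 0.189 with an estimated correlation, which ends the call) and with 0 members past the threshold, also when adjusted over the list alone. Bmp7 had a log2 difference of 1.18 (adjusted p = 0.138) and the signal transducer Smad5 of 0.84 (adjusted p = 0.119). The hedgehog list did not pass (adjusted p = 0.715), although it did as lower with equal peak numbers (0.0313) and with the upper part of each list (0.0138), and its median of 0.07 differed in sign from its mean of -0.09 and its test. Boc was its 1 member that fell. Gli1, a hedgehog target, had a log2 difference of 0.27 (adjusted p = 0.724), Gli2 of -0.94 (adjusted p = 0.146) and Ptch1 of 0.70 with 3.5 against 1.75 peaks (adjusted p = 0.191). The direction turned at Gli1 at gene ends (-0.284), and at Ptch1 with equal peak numbers (-0.25), the upper part of each list (-0.289) and a peak in at least 4 libraries (-0.256). The Wnt list did not pass (adjusted p = 0.694), although its co-receptor gene Lrp6 rose (0.585, adjusted p = 0.022) and Tcf7l2 (0.88, adjusted p = 0.0859) joined it when adjusted over the list alone, which gave 2. The Notch list did not pass (adjusted p = 0.751), with 2 higher and 1 lower when adjusted over the list alone. Notch1 had 1.26 (adjusted p = 0.102) and Lfng, which modifies Notch receptors, -1.03 (adjusted p = 0.133).

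Of the remaining lists, the immediate early genes did not pass camera (adjusted p = 0.434), with Nr4a1 as the member that rose at 4.0 against 1.5 peaks (log2 difference 0.96, adjusted p = 0.0075). Adjusted over the list alone 2 rose, Egr2 being the other (0.81, adjusted p = 0.0651 over all genes), and fry gave this list an adjusted p of 0.00635. Lists of cells of other origin did not pass either, with adjusted p-values of 0.259 for endothelial and mural, 0.262 for microglia and macrophage, 0.608 for ependymal and ciliated, 0.715 for fibroblast and meningeal and 0.755 for lymphocyte genes. The leukocyte genes Ptprc (0.98, adjusted p = 0.153) and Irf8 (0.71, adjusted p = 0.189) did not pass. Cell cycle genes (adjusted p = 0.715) and inhibitors with quiescence genes (adjusted p = 0.784) did not pass. Housekeeping genes had an adjusted p of 0.942 and a test opposite in sign to their median of 0.07 and mean of 0.02.

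Of the 37 genes described above that passed, 28 kept the call with each library left out in turn. Equal peak numbers gave 243 passing genes, of which 46 were among the 233, and 9 of the 30 described genes still tested passed. The call was lost for Sox2 without SOX2- replicate 1, 2 or 4 or SOX2+ replicate 1, with an adjusted p of up to 0.0777 over all libraries left out, and for Olig2 (0.050) without SOX2+ replicate 1. Nhlh1 (up to 0.059) and Lrp6 (up to 0.0668) lost it without SOX2- replicate 2 or SOX2+ replicate 1. Aldh1l1 lost it without any of the 12 libraries (up to 0.168) and Sfrp1 without any but SOX2- replicate 3 (up to 0.124). Ptprz1 (up to 0.0852), Boc (up to 0.107) and Map2 (up to 0.104) lost it without SOX2- replicates 2 or 4, SOX2+ replicate 1 or either SOX2+/MKI67- replicate. Further, Ptprz1 lost it without SOX2+ replicates 2 or 3, Boc without SOX2- replicate 3 or SOX2+ replicate 2, and Map2 without SOX2- replicate 3 or SOX2+ replicates 3 or 4. The number of passing genes fell to 92 without SOX2+ replicate 1, 116 without SOX2- replicate 2, 150 without SOX2+ replicate 4, and 132 and 133 without SOX2+/MKI67- replicates 1 and 2. It was 94 with the upper part of each list by score, 42 at gene ends and 0 with the replicate number as a block (limma, 1772 genes at an unadjusted p under 0.05 against 1957 without the block).

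List calls also depended on other settings. With equal peak numbers the BMP and TGF-beta genes lost the call (adjusted p = 0.214) along with stem and astrocyte genes, and 6 lists passed, 2 higher and 4 lower, of which 3 were among the first 6. The others were hedgehog genes (lower, 0.0313), ependymal genes (higher, 0.0466, 4 tested) and endothelial genes (lower, 0.0466, 1 tested). At gene ends only granule neuron progenitor and stem genes passed. BMP and TGF-beta genes lost the call also without SOX2- replicate 3 (0.226), SOX2+ replicate 2 (0.0621), SOX2+ replicate 3 (0.0504) or SOX2+ replicate 4 (0.0643). Over 25 alternatives the adjusted p ranged from 1.95e-06 to 0.0769 for granule neuron progenitors, 3.08e-06 to 0.53 for stem cells, 2.66e-05 to 0.674 for astrocytes, 3.52e-05 to 0.131 for oligodendrocytes, 0.00115 to 0.131 for neurons and 0.00258 to 0.432 for BMP and TGF-beta. Peaks at stem genes made up 25.1 ± 0.51 per 10000 peaks in SOX2+ and 16.5 ± 2.23 in SOX2- libraries (n = 4 each, exact permutation p = 0.0286, adjusted 0.171). Those at oligodendrocyte genes made up 18.8 ± 1.71 and 9.59 ± 1.77 (exact p = 0.0286, adjusted 0.171), and those at granule neuron progenitor genes 12.1 ± 5.25 and 21.4 ± 3.63 (exact p = 0.0571, adjusted 0.171).

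**Figure D3:**
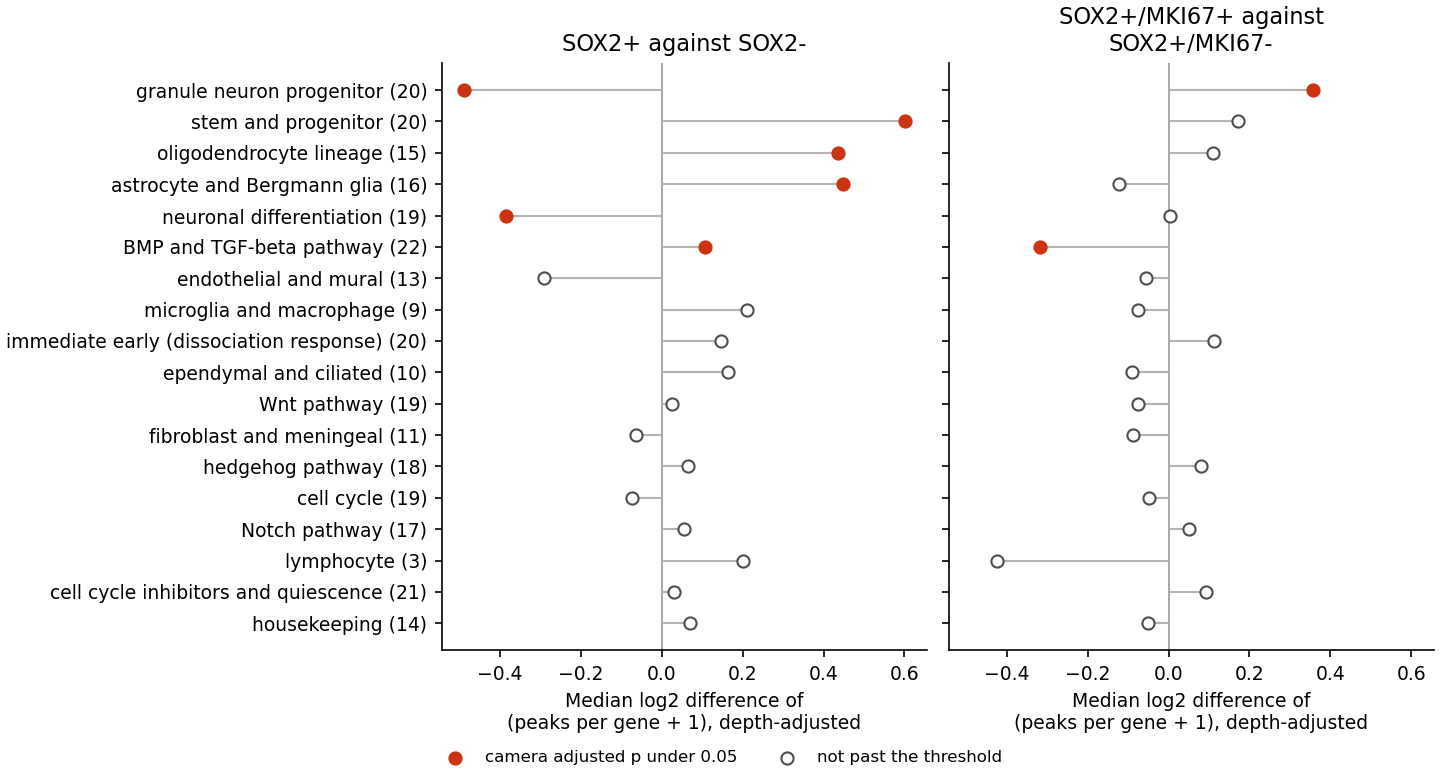
Median log2 difference in peaks per gene for each of the 18 gene lists, with the number of genes tested in parentheses, for the SOX2 sort (left) and the MKI67 sort (right). Filled points are lists with a camera adjusted p under 0.05, of which there were 6 in the SOX2 sort and 2 in the MKI67 sort, and granule neuron progenitor genes have medians of -0.49 and 0.36.

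The mean Jaccard index was 0.412 within and 0.377 between SOX2 groups, a difference of 0.0358 (exact permutation p = 0.171). With equal peak numbers it was 0.516 within and 0.467 between groups, a difference of 0.0494 (exact p = 0.0286). As a share of the shorter list it was 0.916 and 0.792, a difference of 0.124 (exact p = 0.0286).

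Regions exclusive to a group were more numerous in SOX2+ cells. There were 1814 regions listed in at least 3 of 4 SOX2+ and 0 of 4 SOX2- libraries and 680 in the opposite class. The total was 2494. SOX2+ exclusive regions lay inside gene spans for 52.0%, between genes for 37.3% and at gene ends for 10.7%, and SOX2- exclusive regions for 44.0%, 49.1% and 6.9%. Those with the highest score ranks had Acss1, Ccl25, Ccdc34, Traf3ip2 and Brinp1 as nearest genes for SOX2+ cells. For SOX2- cells the nearest genes were Zbtb7c, Kcnj6, Eps8l3, Git2 and Cdk15. The regions of Acss1, Brinp1 and Git2 lay inside the gene. That of Kcnj6 lay 121783 bp away, past the distance limit of the gene fit. Nckap5, Prex1 and Svil had 5 SOX2+ exclusive regions each, Svil beside 1 SOX2- exclusive region, and Opa1 and Reln had 3 SOX2- exclusive regions each. With 7009 peaks from every list there were 663 and 394, and with 4 of 4 against 0 of 4 there were 711 and 70.

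The excess of SOX2+ exclusive regions depended on single libraries, whose omission also tightens the requirement to 3 of 3. There were 761 and 703 such regions without SOX2+ replicate 1, 802 and 1136 without SOX2+ replicate 3 and 711 and 859 without SOX2+ replicate 4. SOX2- exclusive regions numbered 70 without SOX2- replicate 2, 120 without SOX2- replicate 3 and 71 without SOX2- replicate 4.

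Peaks were unevenly spread over chromosome 13 between the populations. Chromosome 13 held 3.94 ± 0.159% of the peaks in SOX2+ and 3.14 ± 0.407% in SOX2- libraries (n = 4 each, exact permutation p = 0.0286, adjusted over 20 chromosomes 0.286), against 3.80% in SOX2+/MKI67+ and 4.25% in SOX2+/MKI67- libraries. Chromosome 4 also separated the groups, with 6.47 ± 0.034% in SOX2+ and 6.80 ± 0.133% in SOX2- libraries (exact p = 0.0286, adjusted 0.286). By chance 2.86% of chromosomes separate 4 libraries from 4. Among the 5397 regions found in all 12 lists, the 150 on chromosome 13 had a mean score percentile of 53.7 ± 1.97 in SOX2+ and 48.8 ± 2.21 in SOX2- libraries (exact p = 0.0286, adjusted 0.286), the largest shift of the 20 chromosomes. Percentiles of the fold ratio, in which a change shared with the local background can cancel, were 56.3 ± 2.57 and 55.3 ± 1.77 (exact p = 0.571).

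The shift lay in the proximal part of the chromosome. Up to 80 Mb the score percentile was 57.6 ± 0.10 in SOX2+ and 44.8 ± 5.01 in SOX2- libraries (68 regions, n = 4 each, exact p = 0.0286), and from 80 Mb on it was 50.4 ± 3.59 and 52.1 ± 1.64 (82 regions, exact p = 0.40). In the first 60 Mb, 42 of 44 regions (95.5%) had a lower mean in SOX2- libraries, against 49.3% of all 5397 regions. The 3 segments of 20 Mb there had the lowest differences of the 141 segments in the genome that held at least 8 regions. They were at -13.3, -19.3 and -23.8 points, the next lowest being -9.23. Between 60 and 65 Mb, where Ptch1 lies, 1 of 2 regions was lower (mean difference -14.7 points), between 65 and 70 Mb 4 of 4 (-16.7) and between 70 and 75 Mb 5 of 10 (2.59). Per library the first 60 Mb had percentiles of 40.7, 56.3, 52.7 and 41.2 in SOX2- and 69.4, 67.5, 61.2 and 68.3 in SOX2+ replicates 1 to 4. Those of SOX2+/MKI67- were 72.9 and 68.4, and those of SOX2+/MKI67+ were 62.3 and 65.7. Up to 70 Mb 11 of 317 tested genes rose in SOX2+ cells and 0 fell, and 76.0% had a positive difference against 48.7% on other chromosomes. Rnf182, Ptch1 (chr13:63508328-63573460), Smad5 and Id4 lie in this part.

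**Figure D4:**
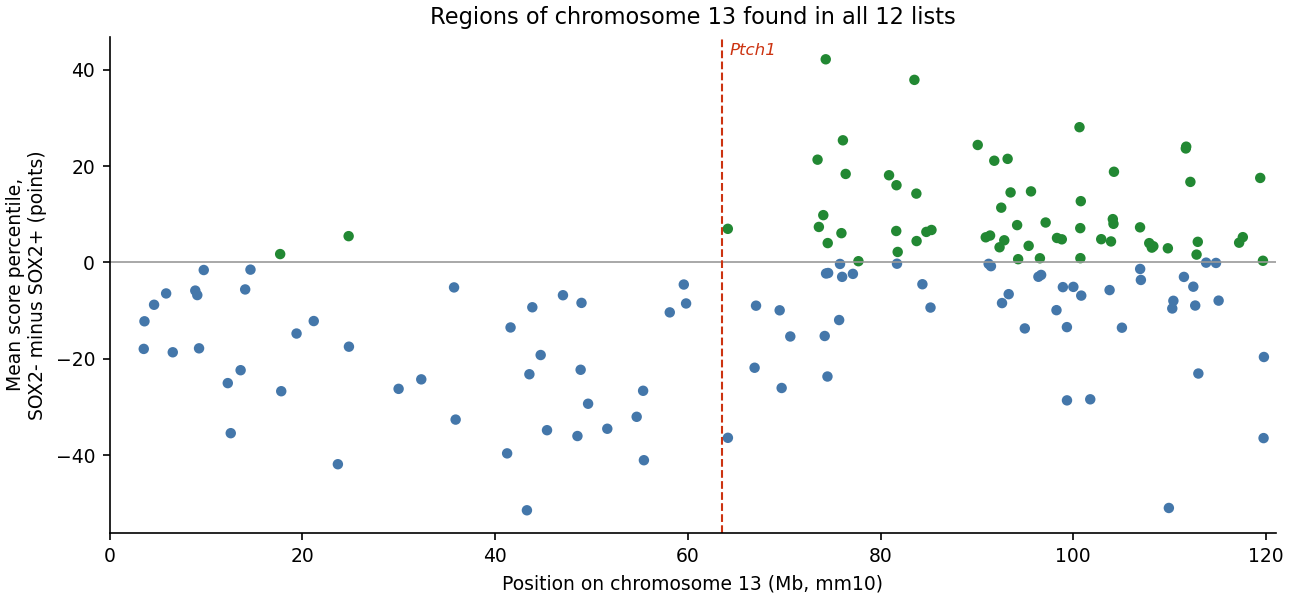
Difference in mean score percentile between SOX2- and SOX2+ libraries (percentile points) for the 150 regions of chromosome 13 found in all 12 lists, by position (Mb, mm10), with 1 point per region and a dashed line at Ptch1. In the first 60 Mb 42 of 44 regions lie under 0, and from 80 Mb on the means are 52.1 in SOX2- and 50.4 in SOX2+ libraries.

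Cycling and non-cycling SOX2+ cells were compared with 2 libraries per group. At the level of genes 0 of 12541 genes passed in limma (smallest adjusted p = 0.293), and 690 had an unadjusted p under 0.05 where 627 would by chance. Granule neuron progenitor loci carried more peaks in MKI67+ cells as a list, and BMP and TGF-beta loci fewer, with the preset correlation of camera only (adjusted p = 0.224 and 0.301 with an estimated correlation). Of the 680 regions exclusive to SOX2- cells in the first sort, 16.2% were found in both MKI67+ and 0.147% in both MKI67- libraries. In no MKI67 library were 50.3% of them found. SOX2+/MKI67+ libraries had 21716 peaks on average and SOX2+/MKI67- libraries 18422 (n = 2 each, exact permutation p = 0.667).

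The marker of the sort, Mki67, had 3.5 peaks in MKI67+ and 1.5 in MKI67- cells (log2 difference 0.64, adjusted p = 0.962), and Sox2 and Olig2 had log2 differences of -0.24 and -0.41, that of Sox2 being 0.20 without SOX2+/MKI67- replicate 2. The largest statistics with more peaks in MKI67+ cells were at Sptb, a spectrin gene listed at 3.5 against 0 (1.76), Ankdd1a at 3.0 against 0 (1.81), Trp73, a relative of p53, at 2.0 against 0 (1.43), Vav1, a guanine nucleotide exchange factor of blood cells, at 2.0 against 0 (1.41), the neuropeptide gene Npy (1.29) and Lsmem1 (1.29). Those with fewer were Ppwd1, Adam5, Apoh, Fam107a, Ifi27 and Myom2, each listed at 0 against 1.0 (-1.0). All 12 had an adjusted p of 0.293. For this sort, equal peak numbers meant 17615 peaks from each MKI67 list, while shorter lists of the SOX2 sort entered the fit whole. In that setting 52 genes passed, 16 higher and 36 lower. Among genes with a peak in at least 4 libraries 39 passed, 24 higher and 15 lower.

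Granule neuron progenitor loci had a median log2 difference of 0.36 with 16 of 20 members positive (camera adjusted p = 4.95e-04, and adjusted p = 0.224 with an estimated correlation). Members past the threshold numbered 0 in limma, also when adjusted over the list alone. Atoh1 had 3.0 peaks in MKI67+ and 0.5 in MKI67- cells (1.30, adjusted p = 0.845), the zinc finger gene Zic2 was listed at 1.5 against 0 (1.20), and Mfap4 (0.98) and Boc (0.50) were positive. Atoh1 regions at chr6:64728659-64729276 and chr6:64734220-64734987 were listed in 2 of 2 MKI67+, 0 of 2 MKI67- and 4 of 4 SOX2- libraries, and in 2 of 4 and 3 of 4 SOX2+ libraries. The list lost its call with equal peak numbers (adjusted p = 0.155), the upper part of each list (0.426), gene ends (0.198), a peak in at least 4 libraries (0.632) and fry (0.141), with a range of 3.56e-05 to 0.632 over 25 alternatives. Peaks at its genes made up 18.4 per 10000 in MKI67+ and 10.6 in MKI67- libraries.

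BMP and TGF-beta loci had a median of -0.32 with 19 of 22 members negative (camera adjusted p = 0.0266, and adjusted p = 0.301 with an estimated correlation). Here too 0 members passed when adjusted over the list alone. Bmp2 (-0.86), Tgfb2 (-0.71) and Id4 (-0.56), a target of BMP signalling, were among the negative members. The call was lost without SOX2+ replicate 4 (0.0583), SOX2+/MKI67- replicate 2 (0.207), SOX2+/MKI67+ replicate 1 (0.241) or replicate 2 (0.0885), and in 7 other settings besides the estimated correlation, with a range of 0.00367 to 0.959 over 25 alternatives. The remaining 16 lists had adjusted p-values of 0.575 to 0.927, and with 0 members past the threshold adjusted over the list alone. Among their members were Gap43 with 6.0 against 1.0 peaks (1.75), the stem-cell factor Sox9 with 3.0 against 0 (1.74), Lfng with 2.5 against 0 (1.61), Cd44 (0.93), Gli1 (0.68) and Gfap (-0.67), none of which passed. With the upper part of each list, Sox9 (-0.205) and Lfng (-0.089) turned direction, as did Ankdd1a (-0.11), Trp73 (-0.089) and Mfap4 (-0.089). Wnt and cell cycle lists had medians of -0.08 and -0.05 with means of 0.01 and 0.03, and the tests followed the mean in the first and the median in the other. The endothelial list had a median of -0.06 and a mean of 0.001 with a negative test.

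The mean Jaccard index was 0.564 within and 0.539 between MKI67 groups, with an exact permutation p of 0.333, the smallest that 2 libraries against 2 can give. There were 1784 regions exclusive to MKI67+ and 430 exclusive to MKI67- libraries, a total of 2214. Regrouped with 1 library of each group on either side, the same 4 libraries gave totals of 1341 and 1255. With equal peak numbers the exclusive regions were 891 and 814, a total of 1705, against 1108 and 745 after regrouping. Such counts thus arose in part without a split by MKI67. With a library left out, the requirement loosens to 1 of 1, and the total was 4391 and 4681 without SOX2+/MKI67- replicates 1 and 2, and 6677 and 5288 without SOX2+/MKI67+ replicates 1 and 2. Exclusive regions with the highest score ranks had Gm11232, Pcdh9, Fzd1, Ssr3 and Frk as nearest genes for MKI67+ cells. All 5 were listed in 4 of 4 SOX2- libraries and in 2 or 3 of 4 SOX2+ libraries. The region lay inside Pcdh9, but 267515 bp from Fzd1 and 293328 bp from Frk, past the 100 kb limit of the gene fit. For MKI67- cells the nearest genes were Elmo1 (region inside the gene), Calml3, Shq1, Trpm3 (129220 bp away) and Atp6ap1l. All 5 regions were in 0 of 4 SOX2- and in 2 or 3 of 4 SOX2+ libraries. Of the MKI67+ exclusive regions 83.8% were listed in at least 1 SOX2- library, and of the MKI67- exclusive regions 15.1%, while 78.1% and 79.5% were listed in at least 1 SOX2+ library. The shares in SOX2- libraries were 89.8% and 26.3% with equal peak numbers in the MKI67 lists. Of the regions found in all 4 MKI67 lists 88.0% were listed in at least 1 SOX2- library and 99.8% in at least 1 SOX2+ library.

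SOX2- exclusive regions were listed at 29.7% and 36.2% in the MKI67+ libraries and at 1.62% and 0.441% in the MKI67- libraries. The mean difference was 31.9 points, 18.0 with equal peak numbers in the MKI67 lists and 12.6 with equal peak numbers in all lists. It was 49.3 without SOX2- replicate 2 and 48.6 without SOX2- replicate 4. SOX2+ exclusive regions were listed at 88.0% and 87.2% in MKI67- and at 70.5% and 91.8% in MKI67+ libraries. Their mean difference was -6.45 points, -18.6 with equal peak numbers in all lists and 4.22 without SOX2+/MKI67+ replicate 1.

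**Figure D5:**
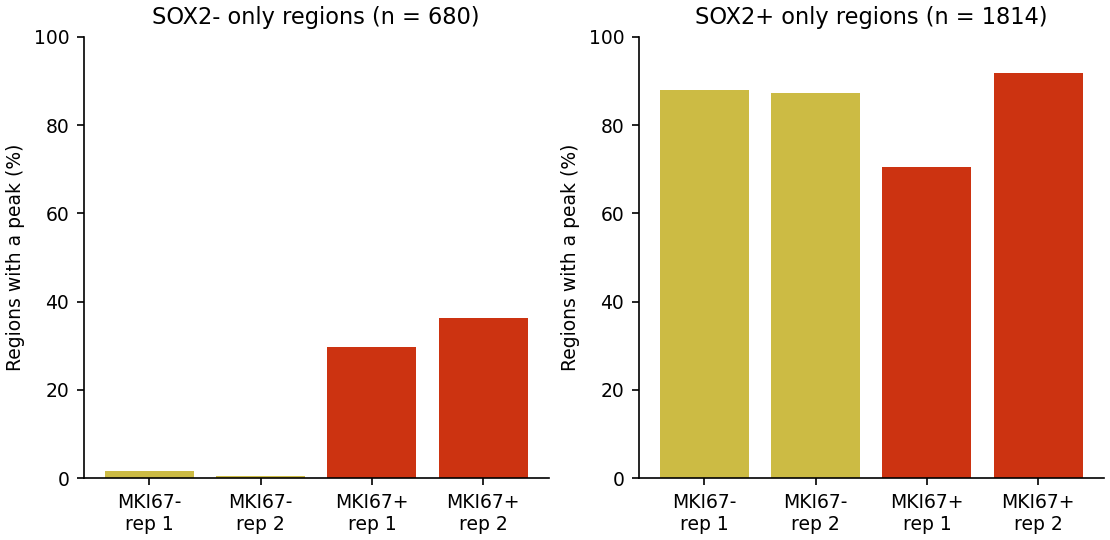
Percent of the 680 SOX2- exclusive regions (left) and of the 1814 SOX2+ exclusive regions (right) with a peak in each of the 4 MKI67 libraries, with 1 bar per library. SOX2- exclusive regions are at 29.7% and 36.2% in MKI67+ and at 1.62% and 0.441% in MKI67- libraries.

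Over the 12541 genes, the log2 differences of both sorts were negatively correlated (Pearson r = -0.20, Spearman rho = -0.15), genes not being independent replicates. Genes that fell in SOX2+ cells had a median log2 difference of 0.28 in the MKI67 sort, with 31 of 52 positive, against -0.02 for genes that rose and -0.05 for all genes.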

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

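Peaks at immediate early genes made up 26.7 per 10000 peaks in SOX2+ replicate 2, far from the 21.4 to 21.9 of the other 3 SOX2+ libraries. The gap to the nearest library was 0.913 of the range of the group, above the 95% critical value of Dixon's test for 4 samples. About 1 in 20 groups exceeds that value by chance. Among 56 groups tested 2.8 would be expected to do so, and 1 did. These genes respond to tissue dissociation among other stimuli. This library also had the shortest SOX2+ list (9377 peaks) and the highest gene-end share of its group (67.2%). No explanation was tested for it. The group values were 22.9 ± 2.49 in SOX2+ and 19.6 ± 1.66 in SOX2- libraries (SD, n = 4 each, exact permutation p = 0.0286, adjusted over 18 lists 0.171).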

How the results depend on the processing

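Alternatives chosen after the data were seen were the shortest list of each SOX2 group left out, the permutation of peaks at list genes and all alternatives of SOX2 exclusive regions in the MKI67 lists. The motif shares planned for both sorts were not run. The causes of the changes given here were not tested, except where fewer peaks or libraries set the count.

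With equal peak numbers the similarity difference of the SOX2 groups was 0.0494 and passed, as it did as a share of the shorter list (0.124), against exact permutation p-values of 0.0857 to 0.314 elsewhere. Exclusive regions of the SOX2 sort numbered 1057 with equal peak numbers and 943 with the upper part of each list, both of which keep fewer peaks, and 781 with 4 of 4 against 0 of 4, a stricter requirement. Those of the MKI67 sort numbered 939 with the upper part. The SOX2- exclusive regions differed between the MKI67 groups by 18.0 points with equal peak numbers in the MKI67 lists and by 12.6 in all lists, and the SOX2+ exclusive regions by -18.6 points in all lists. The correlation of both sorts ranged from -0.113 to -0.256 and kept its sign.

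Genes past the threshold in the SOX2 sort numbered 94 with the upper part of each list, 42 at gene ends, 137 with the libraries of the compared groups alone and 0 with the replicate number as a block (limma, 1772 at an unadjusted p under 0.05). Whether equal replicate numbers mark paired libraries stays open. After removal of group and list length, correlations at equal numbers were -0.0061, 0.406, 0.0786 and -0.18 in the SOX2 sort. Not every library of that sort correlated best with its own number. In the MKI67 sort the correlation was 0.0607 at equal and -0.0607 at unequal numbers. So few libraries cannot settle the question. Equal peak numbers gave 243 genes, of which 46 were among the 233. In the MKI67 sort 52 passed with equal peak numbers in the MKI67 lists and 39 with a peak in at least 4 libraries, where fewer genes were tested.

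Of 18 lists in the SOX2 sort, 2 passed at gene ends, 3 with a peak in at least 4 libraries, and 0 with an estimated correlation (camera, 5 at an unadjusted p under 0.05) or an exact permutation of peaks per 10000 (smallest adjusted p 0.171). The latter count shows little, since the smallest exact p of 0.0286 passes the adjustment only if most of the 18 lists reach it. Equal peak numbers left 6 passing lists, 3 of them among the first 6, with 2 higher and 4 lower in place of 4 and 2. In the MKI67 sort 1 passed with equal peak numbers, without the covariate or with the compared groups alone, and 0 with the upper part, at gene ends, with a peak in at least 4 libraries, with an estimated correlation or with fry (1 to 4 at an unadjusted p under 0.05). The 6 and 2 lists that passed kept their direction in all 25 alternatives each. Of the 12 others in the SOX2 sort, 19 of 300 values had the other direction and 6 passed. Of the 16 others in the MKI67 sort, 49 of 400 had the other direction and 1 passed.

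With each library left out, the difference in peak number ranged from -2414 to 3985. SOX2 exclusive regions ranged from 1464 to 2452 and MKI67 exclusive regions from 4391 to 6677, where 1 library then stands for its group. The difference ranged from 28.7 to 49.3 points for SOX2- exclusive and from -17.1 to 4.22 for SOX2+ exclusive regions. Passing genes ranged from 92 to 258 in the SOX2 sort, and passing lists from 1 to 2 in the MKI67 sort. A lone library left in a group was assumed to vary like the other groups in the limma fit.

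The 37 named genes that passed kept their direction in 809 of 814 values (99.4%), 195 of which no longer passed. Of these 37, 9 of the 30 tested passed with equal peak numbers, 6 of 33 with the upper part, 4 of 23 at gene ends and 9 of 25 with a peak in at least 4 libraries. Reversed values were 0.354, 0.275 and 0.446 for Cacng2 with equal peak numbers, the upper part and a peak in at least 4 libraries, and -0.25, -0.289 and -0.256 for Ptch1 in the same settings. At gene ends they were 0.149 for Tmem178b, 0.005 for Opa1 and -0.284 for Gli1. With the upper part, the MKI67 sort gave -0.11 for Ankdd1a, -0.089 for Trp73, Mfap4 and Lfng and -0.205 for Sox9. With a library left out, Gfap ranged from -0.142 to 0.296 in the SOX2 sort and Sox2 from -0.68 to 0.20 in the MKI67 sort. The other 22 genes of the SOX2 sort kept their direction in 470 of 478 values and the 28 of the MKI67 sort in 583 of 589, with 18 and 10 values past the threshold.

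Depth limits these results through the length of the lists, since a region under the threshold of a short list counts as absent.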

Other observations

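Tests chosen only after their result was seen were those of unequal list lengths, for exclusive regions and for the MKI67 lists, that of chance for the correlation of both sorts, and that of a few loci for the first 60 Mb of chromosome 13, while the test from 80 Mb on took its bound from peak shares already seen. The Olig locus held opposite elements. Beside the 4 regions found in SOX2+ libraries, chr16:91202895-91203314 was listed in 3 of 4 SOX2- libraries and in 0 libraries of the other groups. Several loci held runs of SOX2+ exclusive regions, with 4 each at Astn2 and Megf11, the adhesion gene Dscam, the transcription factor gene Ets1 and Xylt1, which encodes an enzyme of proteoglycan synthesis. Astn2 and Xylt1 also held 1 SOX2- exclusive region each. These counts were not set against the size of the locus.

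SOX2+ cells of the MKI67 sort resembled the SOX2+ cells of the first sort. Their mean Jaccard index was 0.494 to 0.521 to SOX2+ and 0.362 to 0.410 to SOX2- libraries. BMP and TGF-beta genes held 25.0 per 10000 peaks in MKI67- and 20.3 in MKI67+ libraries, against 21.5 ± 2.43 in SOX2+ and 14.4 ± 4.56 in SOX2- libraries (n = 4 each, exact permutation p = 0.0571, adjusted 0.171).

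Chromosome 13 had lower score percentiles in SOX2- libraries, at 48.8 against 53.7, which a lower copy number in SOX2- cells predicts, although the adjusted exact p was 0.286 and the fold ratio, tested first, gave 55.3 against 56.3. Fewer copies of the whole chromosome were argued against by the part from 80 Mb on, at 52.1 in SOX2- and 50.4 in SOX2+ libraries. In the first 60 Mb 95.5% of regions were lower in SOX2- libraries (88.6% to 97.7% with a library left out). That bound was drawn from the same scores, so this share is no independent test of a few loci and does not decide about them. By peak share 5 of 6 segments of 20 Mb were lower in SOX2- libraries, and 4 to 5 with a library left out. A local difference at few loci therefore cannot be told apart by that count. Ratios of SOX2- to SOX2+ shares were 0.80, 0.60, 0.48 and 0.87 along the segments up to 80 Mb. From 80 to 100 Mb, counted as lower, the ratio was 0.9935, and from 100 Mb on 1.09. A candidate explanation is fewer copies, in some SOX2- cells, of the part up to about 70 Mb, although the bin from 60 to 65 Mb, which holds Ptch1, had 1 of 2 regions lower with a mean difference of -14.7 points, too few regions to place Ptch1 inside or outside that part. Copy number was not measured, and a difference in regulation over this part, or more cells without the change in the SOX2+ gate, stays open and untested.

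Glial-lineage loci gained peaks in SOX2+ libraries, which as lists passed camera with the preset and not with an estimated correlation. Markers of oligodendrocyte progenitors had a median log2 difference of 0.981 (bootstrap interval 0.442 to 1.333, 11 of 12 positive). Those of mature oligodendrocytes had 0.236 (0.174 to 0.654, 6 of 7 tested positive). The intervals resample the marker genes and leave out the spread between libraries. Mature oligodendrocytes in the SOX2+ gate may explain part of the gain and cannot be told apart, because their markers lay above 0 but under the progenitors and because 7 of the 12 mature and 11 of the 12 progenitor markers are also in the fixed lists. Of their most abundant genes, Mbp had 3.5 peaks in SOX2+ and 3.75 in SOX2- cells, and Mobp 1.0 and 0. The eGFP gate would remove mature cells without SOX2 but not normal glial progenitors that express it, and a progenitor-like state of tumour cells was not tested against these.

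SOX2- exclusive regions reappeared in part in SOX2+/MKI67+ libraries. Unequal lengths of the MKI67 lists were argued against, since with equal peak numbers the lowest share in an MKI67+ list was 11.3 times the highest in an MKI67- list, and 3.79 times with equal numbers in all 12 lists, where that cause would give no excess. SOX2- cells carried over into the MKI67+ sort predict that the strongest regions return most, and recovery was 32.2 points higher in the upper than in the lower tertile by rank in the SOX2- lists. A cycling SOX2+ state that shares the strongest SOX2- regions predicts the same, so both may hold. The eGFP gate would remove most SOX2- cells, and the share of such cells was not measured.

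Chance was made unlikely for the count of passing genes in the SOX2 sort, where the real split gave 233 and the highest other 0. The real split was 1 of 35, the smallest share that 35 splits can give. That share also held for the exclusive regions (2494 against 2262) and the correlation of both sorts (0.203 in absolute size against 0.182). Both of these margins were narrow, and none of these shares excludes chance. Splits within same-numbered pairs can give no p under 0.125, so they cannot decide if the numbers mark pairs. For the lists 2 of 35 splits gave as many, with 6 in the real split and 6 as the highest other, so chance stays open. The split with 2262 regions followed list length, with SOX2- replicates 1 and 3 and SOX2+ replicates 1 and 2 on one side. With equal peak numbers the real split had 1057 and the highest other 449, which argues against unequal list lengths as the whole source.

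A gain or loss of any whole chromosome in a sorted population cannot be told apart by the count of chromosomes with separate groups, which was 2 of 20. Chance gives 2.86% of chromosomes, the smallest exact p cannot pass the adjustment over 20, and a change of a single chromosome would add only 1 to the count, so a low count excludes nothing.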
